A study of Mus musculus with 6 samples.

How the data were processed

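Gene expression was measured on 6 Affymetrix mouse expression arrays, each hybridised with RNA pooled from the dorsal-lateral prostates of 3 mice aged 7 months. Per the labels, all mice carried Probasin-cre, which acts in prostate epithelium, and one floxed allele of Pten, a tumour suppressor gene. The mice of 3 pools, called Control, carried no further change. Those of the other 3 pools, called SRC-2OE, also carried an SRC-2 overexpression allele at the Rosa26 locus. The labels call the 3 pools of a group biological replicates. RNA was extracted with Trizol and a column, amplified and labelled with biotin, per the labels' protocols.

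The deposited values are intensity values on a linear scale, one per probe set, made with MAS5 per the submitters' processing notes, with a version not given in the sources used here. On each array, the mean of the deposited intensity values without the lowest and highest 2% lay between 499.858 and 499.87, the mark of global scaling to a target of 500. Such scaling sets every array to the same total brightness, so a shift of all genes in one direction would not be seen. The table held no detection calls, and the lowest value of an array lay between 0.0626 and 0.125 and the highest between 30400 and 36376. The median signal of an array lay between 109.6 and 119.4. Depth has no meaning for such values, and the number of arrays limits the precision.

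Each value was taken as log2(signal + 16) with no further normalization, so a fold change is on that scale and understates changes of dim genes. The table held 45101 probe sets, of which 64 were control probe sets and were left out of the gene tests. Genes were named through GEO's annotation of the platform. Of the 45037 other probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none listed. The Entrez identifiers of 34741 probe sets matched the RefSeq gene table of assembly GRCm38.p6 and took its symbols; the others kept the name in the annotation. No coordinates are given, since the build behind the annotation is not given in the sources used here. Each of the 18193 symbols was represented by the probe set with the highest mean among those naming that gene alone. Genes were kept where that mean reached the median of all probe sets, log2 7.009 or a signal of 112.8, which left 11294 genes. Pten itself was not paired with a probe set of 1 symbol and was not analysed here.

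SRC-2OE was tested against Control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with the group as the only term. Errors given with fold changes are limma's standard errors (SE), and those given with group means are standard deviations (SD) over 3 arrays. With 3 arrays against 3, an exact permutation test of a single gene could not pass the threshold, so calls rest on the spread that limma shares over genes. A total of 35 gene lists was fixed, and the 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The rest of the family of tests was camera with a correlation estimated for each list, and fry, which tests whether the members of a list move on balance one way without comparing them with other genes.

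Named genes followed a rule: Ncoa2 and Pten; the 12 called genes with the largest rise and the 12 with the largest fall among those whose groups did not overlap, leaving out unnamed transcripts with Rik, Gm or LOC symbols; and, in each list described by its members, up to 4 members, called ones first and then those with the smallest p. Which lists to describe by counts alone, 12 in all, was decided after the values were seen. The groups, the tests, the lists, this rule and the other settings that follow were chosen before the data were examined. These settings were quantile normalization, median centring, no filter or an upper quartile filter, pseudocounts of 1 and 64, the mean of all probe sets or every probe set, limma without a trend or with robust estimation, array weights, a replicate block, each array left out in turn with the probe set of each gene chosen again, a plain test per gene, and other tests of the lists. Analyses that take account of seminal vesicle transcripts, and 2 gene lists on amino acid and acute phase genes, were added after the data were seen.

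The fit and the list test were tested on simulated data built on the 11294 genes. Of 50 genes changed at each size, 38% were recovered at 1.5-fold, 74% at 2-fold, 92% at 3-fold and 88% at 4-fold, and 3 of 149 calls were false. The list shifted in the simulation was called and 0 of the others were. That result does not show how camera behaves where the members of a list vary together. In the data, the estimated correlation of the 8 lists that passed camera at the preset correlation ran from -0.044 to 0.926. The data also gave 3171 calls against 149 in the simulation, so the recovery rates need not hold there.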

Results

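The arrays profiled mouse prostates in which SRC-2, a coactivator of nuclear receptors such as the androgen receptor, was or was not overexpressed, per the labels, on a background with 1 floxed Pten allele. The 6 arrays fell into 3 Control and 3 SRC-2OE pools, each of RNA from 3 mice. The comparison asks how the prostate transcriptome differs when SRC-2 is overexpressed, as far as the labels state its purpose. Pearson correlations between arrays, taken across the 11294 genes tested, which are not independent replicates, ran from 0.953 to 0.983 within groups and from 0.905 to 0.958 between groups. The first principal component held 62.1% of the variance and separated the groups, with the array SRC-2OE 1 at 7.19 between the Control arrays, at -32.4 to -19.2, and the other SRC-2OE arrays, at 31.5 and 41.1.

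Ncoa2, the gene that encodes SRC-2, showed no measurable rise on these arrays. Its brightest probe set stood at log2 11.09 ± 0.04 in Control and 11.16 ± 0.10 in SRC-2OE (SD, n = 3 arrays each; log2 fold change 0.06, SE 0.07, limma adjusted p = 0.542). The 95% interval of that difference reached up to 1.18-fold. The 3 dimmer probe sets gave log2 fold changes of -0.33, -0.17 and 0.16, and none passed the test. A probe set outside the part of the transcript that a transgene carries cannot measure it, and where these probe sets lie was not examined, so Ncoa2 does not check the labels here. The direction of every value that follows rests on the labels. The mean of all Ncoa2 probe sets gave a log2 fold change of -0.07.

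Expression differed widely between the groups. In SRC-2OE prostates, the potassium channel gene Kcnj15 rose 8.87-fold and the lactase gene Lct fell 13.5-fold (SE 0.52 and 0.42 on the log2 scale, n = 3 arrays each). Of 11294 genes tested, 1664 were higher and 1507 lower in SRC-2OE (limma, Benjamini-Hochberg), 28.1% in all, and 305 of the higher and 271 of the lower genes changed at least 2-fold. The groups did not overlap for 3163 of these 3171 genes and for 47.1% of all genes, where chance gives 10%. The median log2 fold change over all genes was 0.02. The counts depend on which arrays are used: they were 1104 higher and 961 lower without Control 1, 1092 and 978 without Control 3, 1101 and 1008 without SRC-2OE 2, and 955 and 898 without SRC-2OE 3, and they were highest, at 1843 and 1696, without SRC-2OE 1. A plain test per gene, which shares no spread between genes, left 885 higher and 665 lower.

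Among the 12 genes with the largest rise, Kcnj15, a potassium channel, rose 8.87-fold (log2 fold change 3.15, SE 0.52, limma adjusted p = 0.00558), and 5.66-fold without Control 1. Its Control mean was dim, at log2 6.30, so the size depends on the pseudocount: the log2 fold change was 3.55 with a pseudocount of 1 and 2.48 with 64. Slc16a12, a monocarboxylate transporter family member, rose 7.12-fold (SE 0.28 on the log2 scale). Serpina3n, a serine protease inhibitor made in the acute phase response, rose 6.27-fold (SE 0.38 on the log2 scale). Padi4, an enzyme that converts arginine to citrulline in proteins, rose 6.14-fold, and Ffar4, a receptor for long-chain fatty acids, rose 5.26-fold. Lrg1, a secreted leucine-rich glycoprotein, rose 4.93-fold to log2 13.11 ± 0.08, and Cp, the copper-carrying ferroxidase ceruloplasmin, rose 4.90-fold to 13.93 ± 0.21. Ly6g2, Acox2 (an oxidase of branched fatty acids in peroxisomes), Cpxm1 and Tmem14a rose between 4.85-fold and 5.09-fold, and Cpxm1 rose 7.35-fold without SRC-2OE 1. Ly6g2 was dim in Control, at log2 6.05, and its log2 fold change was 2.74 with a pseudocount of 1, 2.35 with 16 and 1.71 with 64. Acox2 was dim there too, at log2 6.47, with values of 2.52, 2.29 and 1.81 under the same pseudocounts. Klk1, a tissue kallikrein, rose 5.32-fold on its brightest probe set (log2 fold change 2.41, SE 0.62, limma adjusted p = 0.0267). Of 3 other Klk1 probe sets, 1 gave -0.20 and the others 2.35 and 1.97. Its call was lost whenever either Control 1, 2 or 3 or SRC-2OE 1 or 2 was left out, with values down to -0.20 where that other probe set became the brightest; without SRC-2OE 3 the value was 3.11. With array weights its limma adjusted p was 0.0544.

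Lct, the gene for lactase, fell 13.5-fold from log2 10.51 ± 0.79 to 6.75 ± 0.56 (log2 fold change -3.76, SE 0.42, limma adjusted p = 0.00179), and the log2 fold change was -3.97 with a pseudocount of 1 and -3.26 with 64. Col4a6, a chain of type IV collagen in basement membranes, fell 12.5-fold (SE 0.22 on the log2 scale). Chn2, which switches off Rac GTPases, fell 10.9-fold, and Vnn1, which releases pantothenate from pantetheine, fell 10.3-fold. The call of Vnn1 was lost without Control 1, without Control 3 or without SRC-2OE 3, with limma adjusted p between 0.052 and 0.0555, and with robust limma (0.0507). Its fall was 18.3-fold without SRC-2OE 1 and 6.09-fold without SRC-2OE 2, and that of Chn2 was 18.8-fold without SRC-2OE 1. Slc26a3, an exchanger of chloride for bicarbonate, fell 8.22-fold, and Atp12a, a proton pump of the potassium-exchanging kind, fell 7.36-fold from log2 12.91 ± 0.03 to 10.03 ± 0.70. Gnmt, which uses up S-adenosylmethionine to methylate glycine, fell 6.95-fold, as did Glb1l3. Gsdma, a gasdermin, fell 6.78-fold, and Aass, the first enzyme of lysine breakdown, fell 6.39-fold (9.68-fold without SRC-2OE 1). Klf12, a transcriptional repressor, and Rimklb, a ligase that makes a dipeptide found in nerve tissue, fell 5.71-fold and 5.69-fold.

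**Figure D1:**
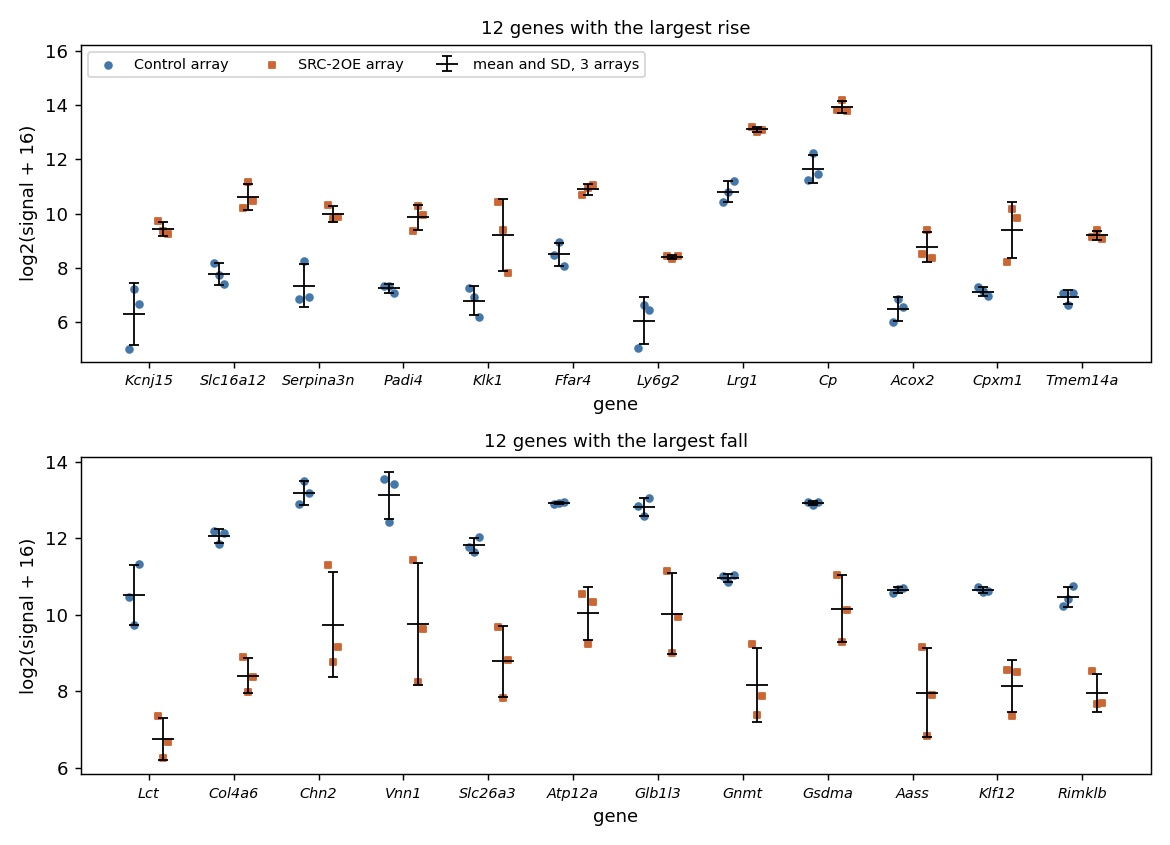
Values of the 12 genes with the largest rise and the 12 with the largest fall in SRC-2OE, as log2(signal + 16) on the vertical axis, with 1 point per array (circles Control, squares SRC-2OE) and bars for the mean and SD over 3 arrays. In each gene the 3 SRC-2OE arrays lie on one side of the 3 Control arrays; for Lct the means are 10.51 and 6.75.

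Several features of the arrays moved with the groups or within them, and stand beside all gene groups below. Smooth muscle markers were lower in SRC-2OE by a median log2 of -1.43, and macrophage markers were higher by 0.82. Secretory transcripts of the seminal vesicle, a gland next to the prostate, were abundant on 1 of 3 Control and 2 of 3 SRC-2OE arrays. The mean of the 7 such genes was log2 14.39 on Control 2, 14.17 on SRC-2OE 2 and 11.06 on SRC-2OE 3, against 4.82 to 5.28 on the other arrays. None of the 7 passed the limma test; Svs4 had a log2 fold change of 3.29 with an SE of 3.22, and Svs5, Pate4 and Svs3a had values of 2.49, 2.60 and 2.07 with SE of 2.81 to 3.14. With these arrays as a block, chosen after the data were seen, 1291 genes were higher and 1154 lower, and 2380 of the 3171 genes remained called. Only the 3 arrays without these transcripts gave 288 higher and 260 lower, and only the 3 arrays with them gave 593 and 460. The former hold 1 SRC-2OE array and the latter 1 Control array, each assumed to vary like the other group. Skeletal muscle markers were highest on SRC-2OE 1 (mean log2 10.37) and Control 2 (9.36). The ratio of the 3' to the 5' control probe sets of Gapdh, a sign of RNA quality, was log2 -0.02 to 0.07 in Control and -0.22 to -0.14 in SRC-2OE. That of actin was 0.891 to 1.12 in Control and 0.74 to 0.847 in SRC-2OE.

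**Figure D2:**
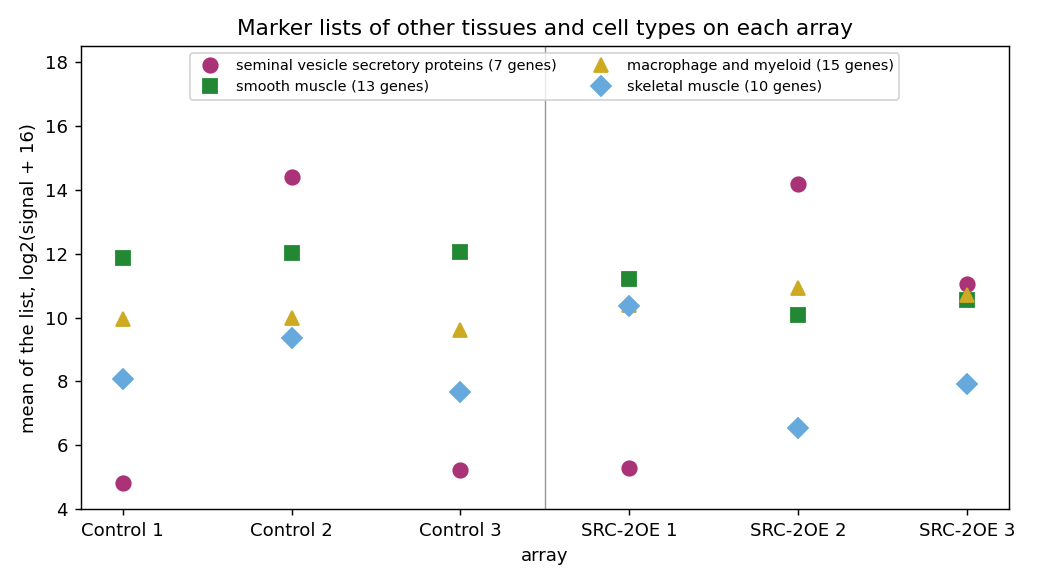
Mean of log2(signal + 16) over 4 marker lists (vertical axis) on each of the 6 arrays (horizontal axis, Control left of the line, SRC-2OE right); each symbol is 1 list on 1 array. Seminal vesicle transcripts lie at 14.39, 14.17 and 11.06 on Control 2, SRC-2OE 2 and SRC-2OE 3 and near 5 elsewhere, and smooth muscle markers are lower on each SRC-2OE array (10.08 to 11.22) than on each Control array (11.87 to 12.04).

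Of 32 gene lists tested, 8 passed camera at the preset correlation, 5 of them higher and 3 lower in SRC-2OE. None of the 8 passed with a correlation estimated for each list, and 7 lists passed fry. For the progenitor-like and glycolysis lists the estimated correlation was -0.044 and 0.0074, below the preset 0.01. A correlation above the preset was therefore not what ended the calls of those lists under that setting. The list of progenitor-like luminal genes and genes induced in prostate epithelium by Pten loss was higher: 11 of 15 members rose and 1 fell, and the counts adjusted over the list alone were also 11 and 1 (median log2 fold change 0.98, camera adjusted p = 0.000437, adjusted p = 0.42 with an estimated correlation). Sprr1a, a cornified envelope protein, rose 3.78-fold, Krt7, a keratin of simple epithelia, 3.31-fold, Cyp2f2, a cytochrome P450, 3.13-fold, and Wfdc2, a secreted protease inhibitor, 2.54-fold. The luminal and basal epithelial lists did not pass camera. Of 16 luminal markers 5 rose and 3 fell (6 and 4 adjusted over the list alone): the transcription factor Elf3 rose by a log2 of 1.29, SE 0.11, and E-cadherin, Cdh1, by 0.31, while Dpp4 fell by 0.94 and Ehf by 0.47. Of 11 basal markers 2 rose and 2 fell (2 and 4 adjusted over the list alone). Krt14 rose by 0.68 and Itga6 by 0.33, while Trp63, a transcription factor of basal cells, fell by 0.48 and Dst by 0.56. With the mean of probe sets the calls of Dst and Itga6 were lost (limma adjusted p = 0.199 and 0.0718). Krt14 lost its call without any 1 array other than SRC-2OE 1, Itga6 without Control 1, Control 3, SRC-2OE 2 or SRC-2OE 3, and Trp63 without Control 2, Control 3, SRC-2OE 2 or SRC-2OE 3. Their limma adjusted p was highest without SRC-2OE 3, at 0.124, 0.0771 and 0.0729.

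Genes of cell division were higher in SRC-2OE. Of 23 cell cycle genes tested, 16 rose and 0 fell, against 18 and 1 adjusted over the list alone (median log2 fold change 0.57, camera adjusted p = 2.01e-05, adjusted p = 0.823 with an estimated correlation). Cdk1, the kinase that drives mitosis, rose 2.33-fold, the proliferation marker Mki67 2.11-fold, Ccna2 1.96-fold and Mcm6, a subunit of the replicative helicase, 1.73-fold. Glycolysis genes were also higher, with 6 of 14 risen and 0 fallen (8 and 0 adjusted over the list alone; camera adjusted p = 0.0083, adjusted p = 0.564 with an estimated correlation). Hk2, which traps glucose in the cell by phosphorylation, rose 2.86-fold with groups of log2 10.08 ± 0.07 and 11.60 ± 0.02. The phosphofructokinase gene Pfkl rose 1.82-fold, the pyruvate kinase gene Pkm 1.64-fold and Pdk1, which inhibits pyruvate dehydrogenase, 1.43-fold (limma adjusted p = 0.0865 with the mean of probe sets). On only the 3 arrays with seminal vesicle transcripts, 1 of them Control, the glycolysis list did not pass (camera adjusted p = 0.0997). The hypoxia list had 5 of 15 genes risen and 0 fallen (6 and 0 adjusted over the list alone) and missed the threshold (camera adjusted p = 0.0683); Egln3 rose by a log2 of 0.95, Pdk1 by 0.52, Bnip3 by 0.45 and Kdm3a by 0.42. It passed without Control 1 (0.0384), without SRC-2OE 2 (0.0295) and without SRC-2OE 3 (0.0471). Without SRC-2OE 3 the calls of Bnip3 and Kdm3a were lost (limma adjusted p = 0.0585 and 0.0541), and without Control 1 that of Kdm3a (0.051).

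**Figure D3:**
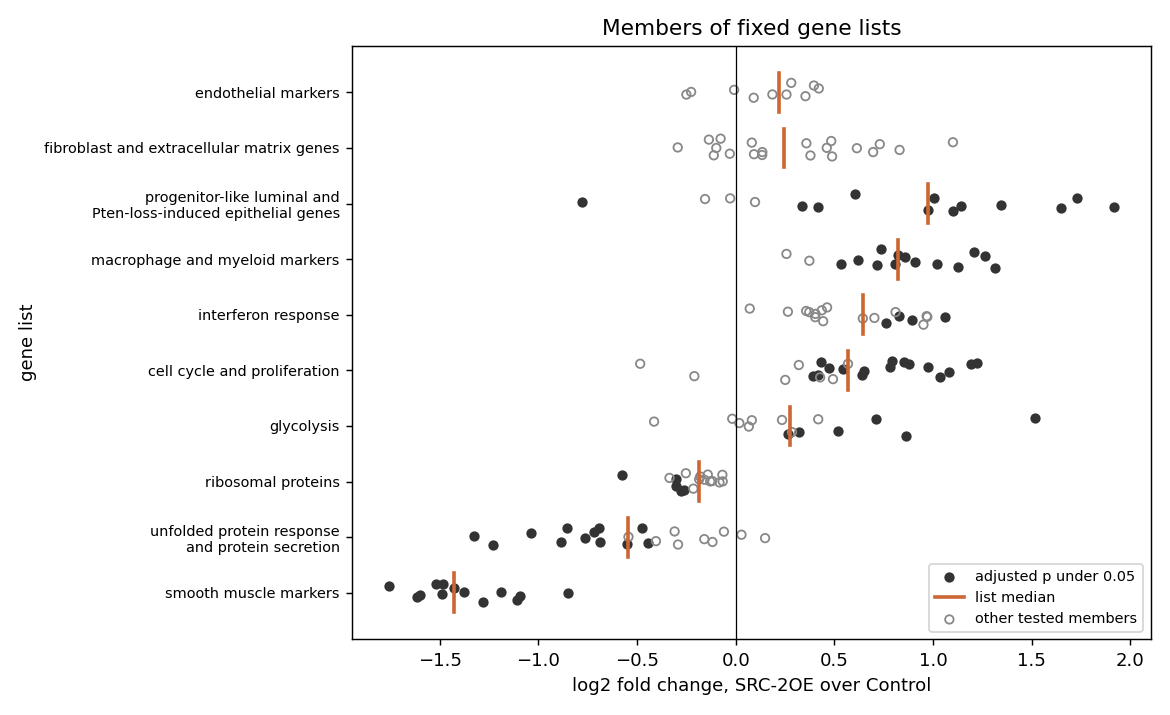
Log2 fold change of SRC-2OE over Control (horizontal axis) for each tested member of the 8 lists that passed camera at the preset correlation and of the fibroblast and endothelial lists (vertical axis); filled points passed limma's test, open points did not, and the bar is the list median. The 13 smooth muscle markers all lie below 0, with a median of -1.43, and no fibroblast or endothelial marker passed.

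Markers of stromal and immune cells went separate ways. All 13 smooth muscle markers fell, and all 13 also adjusted over the list alone (camera adjusted p = 3.39e-06, adjusted p = 0.823 with an estimated correlation); fry gave an adjusted p of 0.0571. The contractile genes Myl9, Myh11 and Mylk fell 2.86-fold, 2.81-fold and 2.79-fold, and Synm, an intermediate filament gene, 2.59-fold. None of 20 fibroblast and matrix genes passed limma, either over all genes or adjusted over the list alone, with a median log2 fold change of 0.25; the collagen genes Col3a1, Col5a2, Col1a2 and Col1a1 had values of 0.73, 1.10, 0.49 and 0.83 (SE 0.19 to 0.37). Those 4 genes passed when SRC-2OE 1 was left out (limma adjusted p = 0.00743, 0.00661, 0.0346 and 0.0138). None of 10 endothelial markers passed either. Macrophage and myeloid markers were higher: 13 of 15 rose and 0 fell, likewise adjusted over the list alone (median 0.82, camera adjusted p = 1.07e-05, adjusted p = 0.823 with an estimated correlation). The endotoxin receptor Cd14 rose 2.49-fold, the Fc receptor chain Fcer1g 2.40-fold, the complement gene C1qc 1.88-fold and Cd68 1.81-fold. Of 19 interferon response genes, 4 rose and 0 fell, and the same counts held adjusted over the list alone (median 0.64, camera adjusted p = 0.00682, adjusted p = 0.823 with an estimated correlation). These were Rtp4, Oasl2, the proteasome gene Psmb8 and Irf9, with rises between 1.70-fold and 2.09-fold. The mean of the list was log2 10.34, 10.1 and 9.61 on the Control arrays and 10.04, 10.98 and 10.9 on the SRC-2OE arrays, so SRC-2OE 1 lay below Control 1 and Control 2. Psmb8, Rtp4 and Oasl2 lost their calls without Control 2, Control 3, SRC-2OE 2 or SRC-2OE 3, with limma adjusted p up to 0.0726, 0.108 and 0.121. The interferon list did not pass on only the 3 arrays without seminal vesicle transcripts, 1 of them SRC-2OE (camera adjusted p = 0.819).

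Genes of protein folding and secretion were lower. Of 21 genes of the unfolded protein response and secretion, 12 fell and 0 rose, against 14 and 0 adjusted over the list alone (median log2 fold change -0.54, camera adjusted p = 6.24e-05, adjusted p = 0.823 with an estimated correlation). Sdf2l1, a protein of the endoplasmic reticulum, fell 2.51-fold, the stress sensor Atf6 2.34-fold, the transcription factor Atf4 1.61-fold and Sec61b, part of the channel that takes secreted proteins into the reticulum, 1.36-fold. With the mean of probe sets the call of Atf4 was lost (limma adjusted p = 0.129). Ribosomal protein genes were slightly lower: 5 of 17 fell and 0 rose, as adjusted over the list alone (median -0.18, camera adjusted p = 0.00411, adjusted p = 0.823 with an estimated correlation). Rpl37 fell 1.49-fold, and Rpl11, Rpl6 and Rps18 by 1.21-fold to 1.23-fold. Rpl11, Rpl6 and Rps18 lost their calls without Control 2, Control 3, SRC-2OE 2 or SRC-2OE 3, with limma adjusted p up to 0.123, 0.142 and 0.133, and with median centring (0.0733, 0.0914 and 0.0843). Quantile normalization ended the call of this list (camera adjusted p = 0.341), and so did using only the arrays without seminal vesicle transcripts, 1 of them SRC-2OE (0.149).

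Lists tied to androgen action did not pass camera, though single members changed in both directions. Over all genes tested 28.1% were called. The androgen receptor gene Ar and the list member Nkx3-1 were not among the genes tested. Of 23 androgen-responsive genes, 3 rose and 4 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.573). Pmepa1 rose 2.24-fold, Steap4, a metalloreductase, 2.02-fold and Maf 1.56-fold, and Ell2, a transcription elongation factor, fell by 0.68 on the log2 scale. Azgp1, Eaf2 and Mme also fell, with log2 fold changes of -1.91, -0.86 and -0.71, and are named beyond the rule. With the mean of probe sets the calls of Ell2 and Maf were lost (limma adjusted p = 0.919 and 0.645). Of 14 prostate secretory genes, 2 rose and 3 fell (2 and 5 adjusted over the list alone). Their median log2 fold change was -0.51 (camera adjusted p = 0.236). Azgp1, given above, is also a member that fell. The members Ceacam10 and 9530003J23Rik were highest on Control 2 and SRC-2OE 2, where seminal vesicle transcripts were abundant (SE 1.86 and 1.14). Fgl1, a secreted fibrinogen-like protein, fell 3.33-fold and Agr2, a disulfide isomerase, 2.47-fold, while Apof rose 1.54-fold and Gdpd1 1.35-fold. Agr2 lost its call without Control 2 or Control 3 (limma adjusted p = 0.0569 and 0.0615), and Gdpd1 without Control 1, Control 3 or SRC-2OE 3 (0.0752, 0.0508 and 0.0762). Among 11 coactivators, nuclear receptors and their partner factors, 2 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.556). Gata2, a pioneer factor of the androgen receptor, fell 2.25-fold from log2 12.21 ± 0.07 to 11.04 ± 0.07. The estrogen receptor gene Esr1 fell 1.84-fold, the prostate homeobox gene Hoxb13 fell by 0.68 on the log2 scale, and the acetyltransferase gene Crebbp rose 1.24-fold. Crebbp lost its call without Control 1, Control 3 or SRC-2OE 3 (limma adjusted p = 0.0563, 0.0577 and 0.0521).

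The signalling and metabolic lists that follow did not pass camera. In the PI3K, AKT and mTOR list 3 of 24 genes rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.377). Irs1, which couples insulin and growth factor receptors to PI3K, fell 3.60-fold, the translation repressor Eif4ebp1 1.88-fold and the AKT phosphatase Phlpp1 1.58-fold, while the regulatory subunit Pik3r3 rose 1.78-fold. Of 14 MAPK output genes 4 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.189): the MAPK phosphatases Dusp4 and Dusp6 rose 3.24-fold and 1.69-fold, Phlda1 1.43-fold and cyclin D1, Ccnd1, 1.31-fold. Ccnd1 lost its call without any 1 array other than SRC-2OE 1 (limma adjusted p between 0.0686 and 0.0876), and Dusp6 without SRC-2OE 3 (0.0571). Of 17 fatty acid synthesis genes 4 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.426), namely the desaturases Fads2 (1.97-fold) and Scd1 (1.40-fold), the malic enzyme gene Me1 (1.72-fold) and the lipogenic factor Srebf1 (1.38-fold). Fads2 lost its call without Control 1, Control 3, SRC-2OE 2 or SRC-2OE 3 (limma adjusted p up to 0.0879), and Scd1 without Control 1, Control 3 or SRC-2OE 2 (up to 0.0766). Me1 lost its call without Control 2, SRC-2OE 2 or SRC-2OE 3 (up to 0.0654), and Srebf1 without Control 1 or SRC-2OE 3 (up to 0.0545). In the list of the TCA cycle and glutamine metabolism 3 of 24 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.586). Idh1 and Idh3a, isocitrate dehydrogenases, rose 1.62-fold and 1.54-fold, while Sucla2 and Fh1, enzymes of the cycle, fell 1.86-fold and 1.42-fold. Of 19 antioxidant and glutathione genes 7 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.556): Gsta3 rose 3.31-fold, Gpx2 2.12-fold and catalase, Cat, 1.65-fold, and Gstm2 fell 1.91-fold. Of 16 genes of mesenchymal transition and invasion 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.426). Timp1, an inhibitor of metalloproteinases, rose 3.86-fold, Tgfb1 2.20-fold and the membrane metalloproteinase gene Mmp14 1.72-fold, and the repressor Zeb1 fell 1.57-fold (limma adjusted p = 0.0605 with the mean of probe sets).

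Of 11 neuroendocrine markers 1 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.109). The list leaned lower, with a median log2 fold change of -0.77 and quartiles of -0.94 and -0.51. Sox2 rose 2.38-fold and Ncam1 fell 1.69-fold, and Snap25 and Scg5 had log2 fold changes of -1.31 (SE 0.48) and -0.95 (SE 0.37) that did not pass. Ncam1 lost its call without Control 1 or Control 3 (limma adjusted p = 0.0655 and 0.0599), while Snap25 passed without Control 3 (0.0469) or SRC-2OE 1 (0.041) and Scg5 without Control 3 (0.0279). The list passed as lower in SRC-2OE with array weights, with a replicate block and without Control 3 (camera adjusted p = 0.0344, 0.00116 and 0.0112). The remaining lists are given by counts of members risen and fallen past limma's threshold, then adjusted over the list alone. Oxidative phosphorylation had 0 and 3 of 33 (0 and 1; camera adjusted p = 0.0802), and its list passed without Control 1 (0.0195) and without SRC-2OE 1 (0.0379). Cholesterol synthesis had 2 and 3 of 17 (2 and 3; 0.391), clock genes 3 and 3 of 16 (5 and 4; 0.866), and immediate early genes 3 and 0 of 18 (3 and 0; 0.407). Schwann cell markers had 1 and 3 of 5 (1 and 4; 0.322), B and plasma cell markers 0 and 1 of 6 (0 and 1; 0.433), and both lists passed without SRC-2OE 3 (0.0406 and 0.0478). Neutrophil markers had 0 and 0 of 5 (0 and 0; 0.553), endothelial markers 0 and 0 of 10 (0 and 0; 0.391), and skeletal muscle markers 0 and 0 of 10 (0 and 0; 0.640). The skeletal muscle list passed without SRC-2OE 1 (0.0458). Seminal vesicle transcripts had 0 and 0 of 7 (0 and 0; 0.613), fibroblast and matrix genes had a camera adjusted p of 0.366, and the luminal and basal lists 0.770 and 0.973. Too few members were tested of the adipocyte (0 risen and 1 fallen of 4), urothelial (0 and 0 of 4) and T and NK cell lists (1 and 0 of 3). In the lists of cofactors, androgen-responsive genes, basal markers, luminal markers, skeletal muscle markers and clock genes, the median, the mean and the test did not all have one sign.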

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

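The values in this part come from probe sets that the comparisons above did not use; all were looked at only after the gene-level results were seen. The array carries 3 control probe sets for Gapdh, a glycolysis enzyme, and each was higher in SRC-2OE than in Control. The log2 fold changes were 0.35 for the 3' set, 0.55 for the 5' set and 0.57 for the middle set (SE 0.07 each, limma adjusted p = 0.0143, 0.00286 and 0.00263). For each set, 3 of 3 SRC-2OE arrays lay above every Control array. They kept this direction under quantile normalization (0.39, 0.60 and 0.61) and median centring (0.33, 0.53 and 0.55). The other way, 36 of 36 bacterial and phage spike-in probe sets above the filter had log2 fold changes below 0, from -0.61 to -0.12. These sets control labelling and hybridisation, and 0 passed limma's adjusted threshold (5 at an unadjusted p under 0.05). Their median was -0.28, beside list medians of -0.18 for ribosomal and 0.27 for glycolysis genes. The values were not rescaled to these sets, so whether scaling moves small fold changes or the counts was not tested that way. Several of the spike-in sets measure the same spiked transcript on the same arrays, so the 36 are not separate observations. Of 3103 probe sets above the filter that name several genes or have none listed, 396 were higher and 279 lower in SRC-2OE (limma), 21.8% in all.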

How the results depend on the processing

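The settings that take account of seminal vesicle transcripts were chosen after seeing the data. Of 123 named genes other than Ncoa2, taken under each setting, 2312 values kept their direction and their side of the threshold, 214 no longer passed, 17 newly passed and 10 turned. Among the list values 667 kept both, 16 no longer passed, 19 newly passed and 26 turned. Leaving out 1 array ended the call of 23 named genes, and 6 uncalled ones passed. All 3171 calls kept their direction under median centring and array weights, which was nearly fixed in advance. The groups did not overlap for 3163 of them, so weights cannot turn those, and median centring shifts arrays little. With the mean of probe sets 98.6% of those tested kept their direction. The filter, the trend, robust estimation and the replicate block leave fold changes as they are. With an array left out in turn, the number of higher genes ran from 955 to 1843 and that of lower genes from 898 to 1696, both lowest without SRC-2OE 3 and highest without SRC-2OE 1. A plain test per gene gave 885 and 665, the arrays without seminal vesicle transcripts 288 and 260, and those with them 593 and 460. The former hold 1 SRC-2OE array, which also has the highest skeletal muscle mean, and the latter 1 Control array, so gains and losses on them rest on a lone array assumed to vary like the other group. The replicate block gave 1378 and 1334. That the numbers were not taken as pairs was set before the data were examined. Deviations of equally numbered arrays correlated by 0.16, 0.341 and 0.0212 across genes, and those of unequally numbered arrays by -0.339 to 0.24. These values do not decide whether the numbers mark pairs. Without a filter, dim genes included, 1461 of 18193 genes were higher and 1321 lower. Ncoa2 ran from -0.068 (the mean of probe sets, which turned it) to 0.17 on the log2 scale. With an array left out, Klk1 ran from -0.20 to 3.11 and Svs3a from -0.044 to 5.38; for Klk1 another probe set became the brightest. Svs5, Pate4 and Svs3a turned with the seminal vesicle block (-0.18, -0.36 and -0.63), and Svs4, Svs5, Pate4 and Svs3a on the arrays with these transcripts (-0.43, -0.44, -1.34 and -2.43). With all arrays kept, other calls were also lost. These were, by limma adjusted p, Krt14 (0.0564) and Rps18 (0.0946) under quantile normalization, Krt14 (0.078), Oasl2 (0.0579), Rpl11 (0.0625), Rpl6 (0.0817) and Rps18 (0.0718) without a filter, and Gdpd1 (0.0512), Rpl6 (0.0581) and Rps18 (0.214) with the mean of probe sets. Without a trend Oasl2 (0.0539), Rpl11 (0.0576), Rpl6 (0.0716) and Rps18 (0.0588) were lost, and with robust limma Oasl2 (0.0533) and Rtp4 (0.0511). The replicate block lost Cdh1, Gdpd1, Krt14, Oasl2, Rpl11, Rpl6, Rps18, Rtp4 and Trp63 (from 0.0517 to 0.113, with Trp63 at 0.052), and the seminal vesicle block Krt14, Oasl2, Rpl11, Rpl6, Rps18 and Scd1 (from 0.0535 to 0.102). Ly6g2 (0.0683) and Cpxm1 (0.0942) were lost on the arrays without seminal vesicle transcripts, and Klk1 (0.186) and Acox2 (0.0631) on those with them, among the genes with the largest rise or fall. The number of lists past camera ran from 0 to 11. With an estimated correlation 0 lists passed, with camera adjusted p of 0.42 for progenitor-like and Pten-loss genes, 0.564 for glycolysis and 0.823 for the smooth muscle, macrophage, cell cycle, interferon, unfolded protein response and ribosomal lists. With fry, the adjusted p no longer passed for smooth muscle (0.0571), the unfolded protein response (0.0865), ribosomal (0.115) and interferon genes (0.302); it passed for cofactors (0.0485), hypoxia (0.0243) and antioxidant genes (0.0126), and clock genes turned (0.974). On the arrays with seminal vesicle transcripts, camera newly called the prostate secretory (0.0108), neuroendocrine (0.00977) and skeletal muscle lists (0.00013) and lost glycolysis (0.0997). There the seminal vesicle (0.0807), luminal (0.851), neutrophil (0.851), immediate early (0.735) and clock lists (0.933) turned. On the arrays without them, hypoxia was newly called (0.0281), interferon (0.819) and ribosomal genes (0.149) were lost, and the skeletal muscle (1.27e-08), basal (0.667), endothelial (0.968) and clock lists (0.86) turned. The block turned the seminal vesicle (0.542) and clock lists (0.86). Without a filter hypoxia passed (0.0176), and basal (0.658) and clock genes (0.896) turned; clock genes also turned with the upper quartile filter (0.813). Basal markers turned with median centring (0.986), the mean of probe sets (0.976) and camera on ranks (0.991). The neuroendocrine list passed with array weights (0.0344) and the replicate block (0.00116), and quantile normalization lost the ribosomal list (0.341). With an array left out in turn, camera adjusted p ran from 0.0959 to 0.969 for seminal vesicle, 0.63 to 0.902 for luminal, 0.63 to 0.916 for basal, 0.0112 to 0.382 for neuroendocrine, 0.0458 to 0.889 for skeletal muscle, 0.0406 to 0.389 for Schwann cell and 0.0478 to 0.694 for B and plasma cell markers. It ran from 0.0195 to 0.29 for oxidative phosphorylation, 0.169 to 0.957 for immediate early, 0.0295 to 0.0974 for hypoxia and 0.694 to 0.999 for clock genes. Directions turned without Control 1 for seminal vesicle and luminal markers, without Control 2 and without SRC-2OE 2 for basal and skeletal muscle markers, and without Control 3 for immediate early and clock genes. For all changes in this part, the cause was not tested. The files hold no detection calls, so the share of genes above background was not analysed here.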

Other observations

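In this part, the lists of amino acid and acute phase genes and the tests of seminal vesicle carry-over, of stroma of every kind and of the place of the Ncoa2 probes were chosen only after related results were seen. A list of genes of amino acid synthesis, transport and loading onto tRNA, with some other ATF4-linked genes, was lower in SRC-2OE prostates. The list held genes linked to the transcription factor ATF4, and 10 members already looked at were left out of the test. Of 32 others, 21 fell and 1 rose (limma), with a median log2 fold change of -0.46 (camera p = 1.513e-09, p = 0.0173 with an estimated correlation). Slc7a1, which imports arginine and lysine, fell by 1.16 (SE 0.13), Aldh18a1, an enzyme of proline synthesis, by 0.78, and the tRNA synthetase genes Lars and Mars1 by 0.72 and 0.69 on the log2 scale. Nupr1, the only member that rose, had a log2 fold change of 0.77 and was named after its value was seen. Over the settings the adjusted p of 2 lists ran from 3.38e-10 to 0.0346. That these genes are lower as a set is a hypothesis found and tested on the same arrays, and ATF4 activity was not measured.

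Genes of the acute phase response linked to the transcription factor STAT3 were higher, with 8 members already looked at left out. Of 24 others, 15 rose and 2 fell (limma), with a median log2 fold change of 0.67 (camera p = 4.577e-05, p = 0.107 with an estimated correlation). Lbp, which binds endotoxin, had a log2 fold change of 1.96 (SE 0.20), Reg3b, a secreted lectin, 1.70, Bcl3, a partner of NF-kB, 1.40, and Stat3 itself 0.77. The members that fell were the metallothionein genes Mt1 (-0.73) and Mt2 (-0.81), named after their values were seen. Over the settings the adjusted p ran from 9.73e-06 to 0.107. That these genes are higher as a set is likewise a hypothesis, its call is lost with an estimated correlation, and STAT3 activity was not measured. Macrophage markers rose as well, and cell types were not separated.

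Seminal vesicle transcripts stood high on Control 2, SRC-2OE 2 and SRC-2OE 3. On Control 2 and SRC-2OE 2, 7 of 7 such genes lay above log2 10, and on the 3 arrays without these transcripts all 7 lay below log2 7; the same genes sort the arrays, so this count does not decide whether carry-over of the neighbouring gland is the source. An effect of the SRC-2OE genotype as the whole cause is argued against, since 0 of the 7 genes were higher on all SRC-2OE than on all Control arrays. For SRC-2OE 3 the source cannot be told apart: its drop from the other high arrays ran from 0.36 (Svs4) to 9.02 (Sva), a range of 8.664 log2 units, but the brightest genes lie near the top of the scale at 15.15.

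The calls between the groups were weighed against possible carry-over of seminal vesicle tissue. The test first set out, the share of all calls with the same direction on the arrays without these transcripts, was void, because groups without overlap (3163 of 3171 calls) fix its outcome, and it was replaced after related values were seen. Of 1053 genes called on the 3 arrays with these transcripts, 982 (93.26%) went the same way on the other 3 arrays, with a median size of 1.10 with and 0.69 without on the log2 scale; each side of this test has a group of 1 array. With these transcripts as a block over all 6 arrays, the median ratio of fold changes with the block to those without was 0.945 and 2380 of the 3171 genes remained called. The block values cannot decide this, since called genes have little spread within groups and these transcripts differ within both groups. Genes that follow these transcripts would seldom be called. The shared direction on separate arrays cannot decide it either. On the 3 arrays with these transcripts both groups hold them, with list means of 14.39 on Control 2 and 14.17 on SRC-2OE 2. They also differ within SRC-2OE, with 11.06 on SRC-2OE 3, so genes that follow them would seldom be called there. The shared direction shows only that most genes called on those arrays went the same way on the others. It rests on groups of 1 array, and genes are not independent. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: the real split called 3171 genes, in 1 of 10 splits, and the highest of the others called 4, the split that follows the seminal vesicle transcripts.

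Ncoa2 was not raised on its probe sets. That SRC-2OE 1 was a whole Control pool with a wrong label is argued against. Its position was taken over 3542 genes called without it on the probe sets chosen with 6 arrays. Between Control (0) and the other SRC-2OE arrays (1), the median position was 0.663, with quartiles of 0.443 and 0.872. This does not bear on a pool that mixed mice of both groups, which was not tested. A wrong label on SRC-2OE 1 would also not explain Ncoa2. Its brightest probe set stood at log2 11.27 on SRC-2OE 1, and at 11.09 and 11.12 on SRC-2OE 2 and 3. The Control arrays stood at 11.07 to 11.14. Probe sets outside the part of the transcript carried by the transgene stay open (log2 fold change 0.06474), since their position was not examined.

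Smooth muscle markers were lower in SRC-2OE. Less stroma of every kind is argued against, as far as marker transcripts follow cell share. The fibroblast and matrix list had a median log2 fold change of 0.2467 and the endothelial list 0.22, against -1.43 for the smooth muscle list. Schwann cell markers had a median of -0.64, with 1 risen and 3 fallen of 5, so smooth muscle was not the only list of this kind to lean lower. Expression per cell was not measured. A lower share of smooth muscle cells and lower expression within them cannot be told apart. The 13 values had an SD of 0.25, and 13.79% of 10000 random lists of 13 called lower genes had one as small. A smaller SD would not have decided it either. These markers vary together (estimated correlation 0.926), and a common fall of expression could also give alike fold changes. An effect of the genotype on the muscle cells stays open and was not tested.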
